A study of Mus musculus with 10 samples.

How the data were processed

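Gene expression was measured in 10 samples of the mouse mammary carcinoma line 4T1, grown in collagen gels of 2 mg/mL (LD, 5 samples) or 3.5 mg/mL (HD, 5 samples). Per the labels' protocols, gels were kept for 5 days at 37 °C and 5% CO2 in RPMI medium with 10% fetal bovine serum, with a medium change on day 3. Total RNA was extracted with Trizol and labelled with biotin as single-stranded cDNA using the Affymetrix WT Plus kit, and hybridised to Affymetrix MTA 1.0 arrays, which carry probes across whole transcripts of coding and noncoding genes. Each sample was 1 array with 1 colour.

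The deposited table holds log2 values, 1 per array and feature, which the authors made with RMA per the submitters' processing notes. RMA subtracts a modelled background, equalises the distribution of probe intensities between arrays and summarises the probes of a feature on the log2 scale. The software, its version, the annotation and the genome build are not given in the sources used here, so no coordinates are printed. That the scale is log2 was taken from the values, which ran from 1.49 to 14.3 with medians of 5.19 to 5.28 per array and none below 0; rows were not centred. RMA compresses folds, so folds given here are ratios of RMA signals. Scanner files, detection calls, scan dates and chip batches were not used here, so a batch that follows the groups could not be looked for. No pair of arrays held identical values. The table had 72688 rows, of which 6732 were control features and 65956 transcript clusters.

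Gene names came from the platform annotation. It listed 32750 rows, of which 30604 named 1 gene symbol after repeats were removed and 2146 named several; 33206 transcript clusters had no symbol there and are unnamed here. Gene IDs of 22818 single-gene rows matched RefSeq's mouse gene table (assembly GRCm38.p6, used for names and gene spans only), and 827 symbols were updated. The rows gave 30142 symbols, 355 of them with more than 1 row. A gene was represented by its row with the highest mean over the 10 arrays, and was tested if that mean lay above the median of all rows' means (log2 5.24). This left 17800 genes. The floor lies above the background rows (3.47 in LD and 3.63 in HD) and below the median of the rows named as negative controls (5.67 and 5.42). What the negative control rows measure is not given in the sources used here.

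HD was compared with LD in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on the deposited log2 values, 2 groups without covariates, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are HD over LD, or LD over HD where a gene is called lower. Errors are the SD over 5 arrays or the moderated SE. The design, the alternatives, 41 gene lists and the rule for naming genes were fixed before the data were examined. The rule took the 12 genes with the largest change in each direction among those past the threshold whose groups did not overlap (3782 higher and 2642 lower genes qualified), leaving out unannotated symbols and pseudogenes (6 among the higher and 1 among the lower). It also took, from each list, the 3 called members with the largest change. Genes named outside the rule are said to be so. Lists with at least 5 tested members (40 of 41) were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Camera was repeated with the correlation estimated from the data, and fry was run beside it. List members with no single-gene row, or below the floor, were not analysed here. The counts of lists cover all lists tested; the result of 1 list that did not pass camera is not described.

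The replicate numbers 1 to 5 in both groups could mark pairs, so the deviations of same-numbered arrays from their group means were correlated over genes. The correlations were 0.19, -0.091, -0.036, 0.22 and -0.025, so the numbers were not treated as pairs.

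The gene test was tested on simulated data with the means and spreads of the 17800 genes of this comparison. Among 50 changed genes per size, it recovered 54% at a log2 change of 0.25, 96% at 0.5, and 100% at 1 and at 2, and 3.31% of all calls were false. Only 200 genes were changed there, and genes varied independently, whereas 50.9% of genes were called in the data. The adjusted threshold depends on that share, so these percentages do not carry over to the real comparison. In a simulation with independent genes, camera recovered both lists shifted by 0.3 and called no other. The alternatives fixed in advance were a replicate block, quantile normalization and median centring of the deposited values, no filter and a stricter filter on dim rows (75th percentile, log2 6.96), averaging the rows of a gene, trended and robust variances, array weights, leaving out each array, a 1.5-fold threshold, ordinary t statistics, all rows named or not, and the other list tests. Alternatives chosen after seeing the data were a linear scaling of each array on its negative and positive control rows (control-row scaling), and leaving out LD replicate 1 and HD replicate 3, whose negative control rows were most extreme.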

Results

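The data were expression profiles of 4T1 cells, an established mouse mammary carcinoma line that grows as an aggressive, metastatic tumour when injected into mice. The cells, 50000 at the start, were cultured for 5 days in gels that held 2 mg of collagen per mL (low density, LD) or 3.5 mg per mL (high density, HD). Total RNA was hybridised to Affymetrix mouse transcriptome arrays. There were 5 LD and 5 HD arrays, each of 1 sample, and all values are log2 signals. The number of arrays, rather than read depth, limits the precision here. Nothing in the labels says that the 5 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The comparison asks how the density of the surrounding collagen changes gene expression in these cells.

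The arrays separated by collagen density. Across the 17800 genes tested, the correlation between arrays (across genes, which are not independent replicates) was 0.9961 to 0.9983 within a group and 0.9835 to 0.9932 between groups. The first principal component held 71.0% of the variance and placed all 5 LD arrays on the other side of all 5 HD arrays. With limma and Benjamini-Hochberg adjustment, 5589 genes were higher and 3467 lower in HD at an adjusted p under 0.05. Most changes were small, with a median absolute log2 change of 0.22 among the called genes, against a median SD between replicates of 0.073. Only 138 genes rose and 278 fell by at least 1.5-fold, and 7 rose and 68 fell by at least 2-fold. The 5 HD values lay wholly above or below the 5 LD values for 6534 genes, 36.7% of those tested, where chance gives 0.794%. Higher genes made up 61.7% of the calls as deposited and 72.1% after quantile normalization, and 33.2% of the calls of at least 1.5-fold. Control features of the array moved with the groups as well. The median of the positive control rows was 9.21 in LD and 9.28 in HD, and that of the rows named ERCC 4.51 and 4.70 (two-sided exact permutation p = 0.0079 and 0.032). The median of the rows named as negative controls was 5.67 ± 0.052 (SD, n = 5) in LD and 5.42 ± 0.12 in HD, and that of the background rows was 3.47 ± 0.055 and 3.63 ± 0.057 (two-sided exact permutation p = 0.0079 for each, the smallest that 5 against 5 arrays can give).

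The largest rise was in Prl2c2, a gene of the proliferin group of prolactin-like secreted hormones. Its signal was 5.83 ± 0.131 (SD, n = 5) in LD and 9.48 ± 0.143 in HD, a 12.6-fold difference (log2 change 3.65 ± 0.0724 SE, limma adjusted p = 1.1e-12). The related Prl2c5 rose from 4.98 ± 0.0749 (SD, n = 5) to 7.84 ± 0.181 (limma adjusted p = 1.7e-11); its LD signal was below the signal floor of 5.24, so no fold is given. These genes are close paralogs that probes may not separate, and the LD signal of Prl2c2 lay near the median of the negative control rows (5.67), which limits its fold. Id1, an inhibitor of basic helix-loop-helix transcription factors, rose 2.22-fold, and Cycs, which encodes cytochrome c, rose 2.20-fold. Atp1b1, a subunit of the sodium pump, rose 2.10-fold. The rest of the 12 genes that rose most did so by 1.84-fold to 1.98-fold. They were P3h2 (a collagen prolyl 3-hydroxylase), Ccne2 (cyclin E2), Timm8a1 (a mitochondrial import chaperone), Pno1 (a ribosome assembly factor), Selp (P-selectin), Mars2 (the mitochondrial methionyl-tRNA synthetase) and Ppbp (a chemokine). In LD the signal of Mars2 (5.30) lay below the median of the negative control rows and that of P3h2 (5.745) near it, which limits their folds. Cycs and Timm8a1 each had 2 rows on the array, which rose by 0.94 and 1.14 and by 0.75 and 0.93 on the log2 scale. Their folds above are those of the brighter row, which rose more. By their identifiers the 2 rows of each gene lie on different chromosomes, and which row measures the gene itself was not tested. The folds of Cycs and Timm8a1 are thus uncertain. On its dimmer row Timm8a1 (0.75) rose by less than Ppbp (0.88), the smallest log2 change among the 12 genes.

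**Figure D1:**
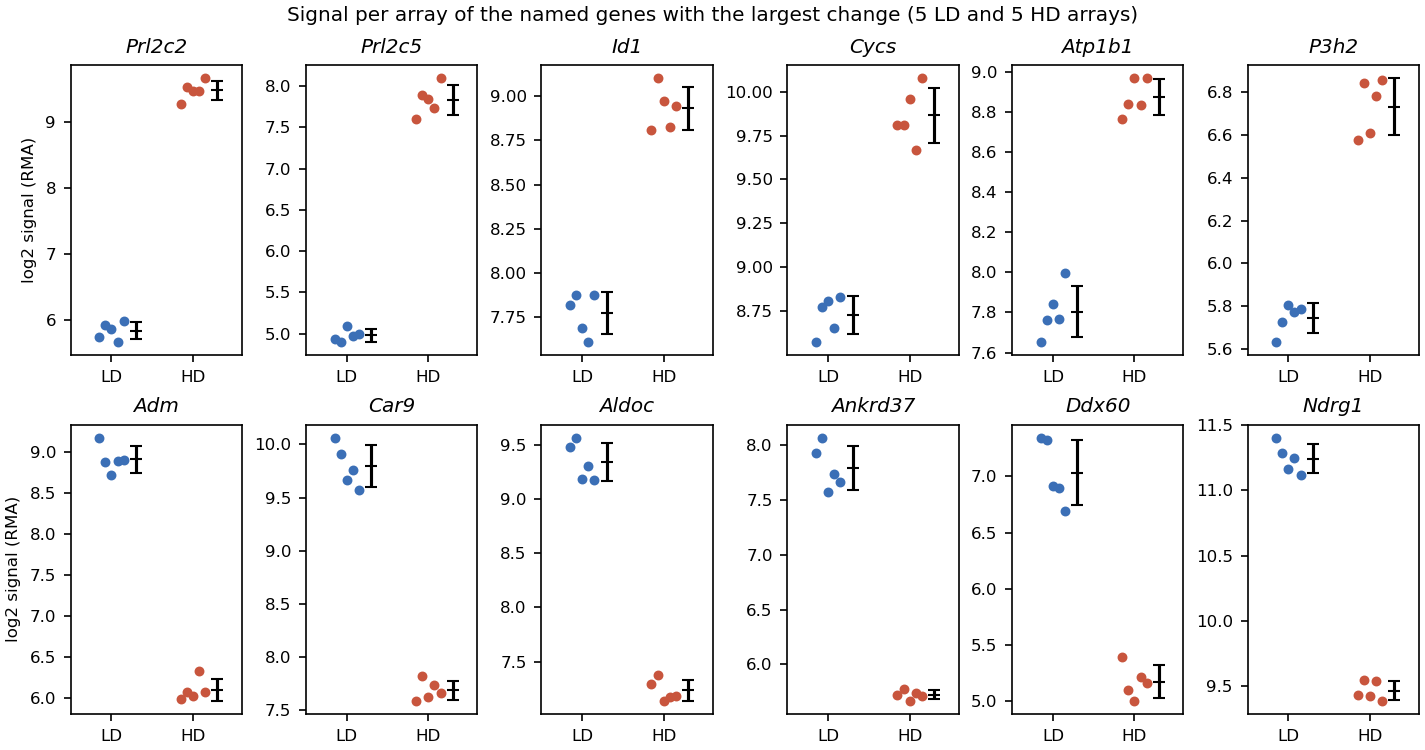
Log2 signal on each array (y axis, RMA values; ranges differ between panels and do not start at 0) of the 6 named genes with the largest rise (top row) and the 6 with the largest fall (bottom row) in 5 LD (blue) and 5 HD (red) samples; bars give the group mean ± SD. In every panel the 5 HD points lie wholly above or below the 5 LD points, with Prl2c2 moving from 5.83 to 9.48 and Adm from 8.92 to 6.10.

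Several of the genes that fell most in HD were genes of the hypoxia response. Adm (adrenomedullin, a secreted vasodilator peptide) had a signal of 8.92 ± 0.164 (SD, n = 5) in LD and 6.10 ± 0.132 in HD, 7.05-fold lower (log2 change -2.82 ± 0.0778 SE, limma adjusted p = 3.2e-11). Car9, the hypoxia-induced carbonic anhydrase IX, was 4.33-fold lower (limma adjusted p = 6.0e-10), and Ankrd37, a HIF-1 target, was 4.21-fold lower. The HD signal of Ankrd37 (5.72) lay near the HD median of the negative control rows (5.42), which limits its fold. Ndrg1, Bnip3 (a mitophagy receptor) and Ddit4 (an inhibitor of mTORC1) were 3.42-fold, 3.33-fold and 3.22-fold lower. Of the 20 tested members of the hypoxia list, 19 fell and none rose, with a median log2 change of -1.06. The remaining member, Selenbp1, named after its value was seen, differed by -0.0047. The list stood apart from other genes by camera with a preset correlation (adjusted p = 5.4e-22), but not past the threshold when the correlation between its genes was estimated (adjusted p = 0.099 with an estimated correlation). Other genes among the 12 that fell most were Gbp2 of the interferon response, Cp (the ferroxidase ceruloplasmin), Ctsw (cathepsin W) and Txnip (an inhibitor of thioredoxin and glucose uptake), 2.89-fold to 3.12-fold lower. Ddx60, an interferon-induced helicase, fell from 7.04 ± 0.288 (SD, n = 5) to 5.18 ± 0.146, below the signal floor, so no fold is given.

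Glycolytic genes fell as a group. Of 19 tested members, 17 fell and none rose, with a median log2 change of -0.39. Aldoc (aldolase C) was 4.30-fold lower, at 9.34 ± 0.176 (SD, n = 5) in LD and 7.23 ± 0.0967 in HD (log2 change -2.11 ± 0.0747 SE, limma adjusted p = 3.1e-10). Pdk1, the kinase that inhibits pyruvate dehydrogenase, was 2.65-fold lower, and Eno2 (enolase 2) 2.12-fold lower. Slc2a1, the glucose transporter GLUT1, and Ldha (lactate dehydrogenase A) fell by 0.95 and 0.25 on the log2 scale. Slc16a3, a lactate transporter, and Pfkfb4, a regulator of glycolytic flux, differed by 0.08 and -0.05 and did not pass the test. These 4 genes were chosen after their values were seen. Camera placed the list below other genes (adjusted p = 1.1e-13), and adjusted p = 0.099 with an estimated correlation. Adjusted over the list alone, the same 19 hypoxia and 17 glycolysis calls were counted as lower. Pdk1 is also a HIF-1 target, and several glycolytic genes are induced by hypoxia.

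Genes of mitochondrial respiration moved the other way. Of 66 tested nuclear genes of oxidative phosphorylation, 55 rose and 1 fell, with a median log2 change of 0.26. Beside Cycs, Uqcrq of complex III rose 1.56-fold (0.64 ± 0.0625 SE, limma adjusted p = 2.2e-06). Atp5l of the ATP synthase rose 1.53-fold (0.61 ± 0.0515 SE) on its brightest row, while its other rows differed by 0.41 and 0.13. By its identifier the brightest row lies on another chromosome than the other rows, so the fold of Atp5l is uncertain. The member that fell was Ndufv3 of complex I, by 0.26, chosen after its value was seen. In the TCA cycle and pyruvate entry list, 14 of 24 members rose and 1 fell, with a median of 0.17. Sdhb and Sdhd, subunits of succinate dehydrogenase, rose 1.42-fold and 1.30-fold, and Idh3a, a subunit of isocitrate dehydrogenase, rose 1.34-fold. Adjusted over the list alone, 55 and 15 members of the 2 lists rose and 1 of each fell. Camera placed both lists above other genes (adjusted p = 1.1e-11 and 0.0034). These became adjusted p = 0.32 and adjusted p = 0.40 with an estimated correlation. When the arrays were scaled on their control rows, the TCA list no longer stood apart (adjusted p = 0.62), with its median at 0.15 and that of all genes tested at 0.13 instead of 0.055. Of 6 tested transcripts encoded by mitochondrial DNA, ND3 rose by 0.18 and ND6 fell by 0.15, and the list did not pass camera (median -0.07, adjusted p = 0.57), except as lower after the control-row scaling (median -0.32, adjusted p = 0.0024). ND3 changed sign under the control-row scaling (-0.15). The ND6 call was lost when any 1 array other than LD replicate 5 or HD replicate 5 was left out, at adjusted p of 0.056 to 0.099. Adjusted over the list alone, ND3 was the single call.

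Serine and one-carbon genes were higher in HD. Of 14 members, 10 rose and 1 fell, with a median log2 change of 0.39. Mthfd2, a mitochondrial folate enzyme, rose 1.74-fold (0.80 ± 0.0658 SE, limma adjusted p = 5.5e-07). Phgdh, the first enzyme of serine synthesis from glycolytic intermediates, rose 1.55-fold, and Gcsh of the glycine cleavage system rose by 0.58 on the log2 scale. In the glutamine and glutamate list, 13 of 16 rose and 1 fell, with a median of 0.31. Its largest rises were in Ppat (1.58-fold) and Cad (1.44-fold), glutamine-using enzymes of nucleotide synthesis, and in Asns (log2 change 0.58), the asparagine synthetase. Of 7 pentose phosphate genes, 6 rose and none fell (median 0.20), led by the transaldolase Taldo1 at 1.31-fold. All 3 counts were the same when adjusted over the list alone. Camera adjusted p were 0.0031, 4.2e-04 and 0.023 for the 3 lists. They were adjusted p = 0.40, adjusted p = 0.25 and adjusted p = 0.32 with an estimated correlation. The glutamine and pentose phosphate calls ended under the control-row scaling (medians 0.28 and 0.17, adjusted p = 0.088 and 0.22), and the pentose phosphate call also after quantile normalization (median 0.20, adjusted p = 0.065).

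Lipid synthesis genes were lower in HD. Of 18 tested cholesterol synthesis genes, 12 fell and none rose, with a median log2 change of -0.29. Insig1, a sterol-regulated inhibitor of SREBP activation, was 2.09-fold lower (-1.06 ± 0.0725 SE, limma adjusted p = 1.3e-07). Lss (lanosterol synthase) and Fdps (farnesyl diphosphate synthase) were 1.49-fold and 1.43-fold lower. Of 13 fatty acid synthesis genes, 7 fell and 2 rose (median -0.13). The stearoyl-CoA desaturase Scd1 was 1.77-fold lower, and the desaturases Fads1 and Fads2 were 1.51-fold and 1.29-fold lower. Dimmer second rows of Scd1 and Fads2 changed by -0.64 and -0.46 on the log2 scale. Counts were the same when adjusted over the list alone. Camera gave adjusted p = 4.4e-08 for cholesterol synthesis and 0.014 for fatty acid synthesis, and adjusted p = 0.25 and adjusted p = 0.32 with an estimated correlation. The fatty acid synthesis call ended with the stricter filter on dim rows (median -0.07, adjusted p = 0.095). Fatty acid oxidation genes went both ways, with 3 higher and 5 lower of 18, over all genes and adjusted over the list alone (median 0.0031, mean -0.02). Acadm and Echs1 fell by 0.37 and 0.32 and Acadvl rose by 0.22, and the list did not pass camera (adjusted p = 0.32).

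**Figure D2:**
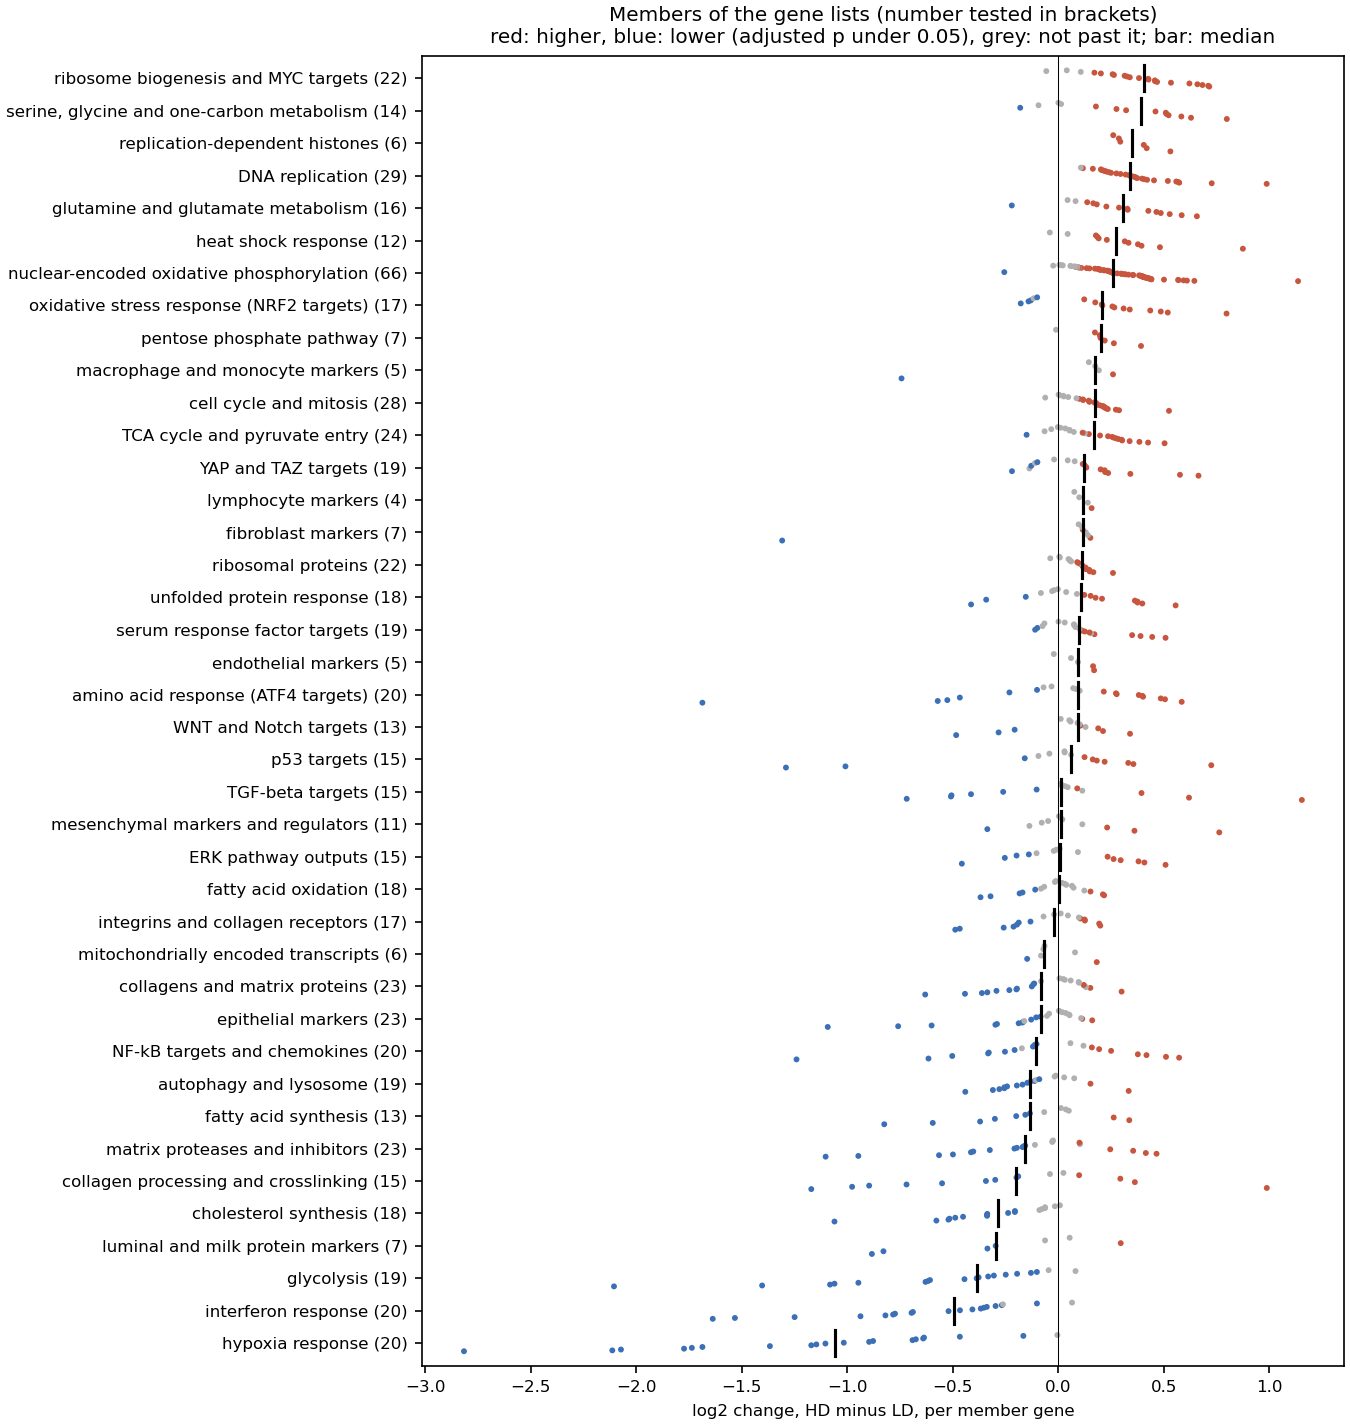
Log2 change (x axis, HD minus LD) of each tested member of 40 gene lists (y axis, number of tested members in brackets, sorted by median); red points were higher and blue points lower at an adjusted p under 0.05, grey points did not pass, and black bars are list medians. The hypoxia, interferon and glycolysis members lie to the left (medians -1.06, -0.49 and -0.39) and those of ribosome biogenesis, DNA replication and oxidative phosphorylation to the right (0.40, 0.34 and 0.26).

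Interferon-response genes were lower in HD. Of 20 tested members, 18 fell and none rose, with a median log2 change of -0.49. Gbp2, a guanylate-binding protein, was 9.15 ± 0.27 (SD, n = 5) in LD and 7.51 ± 0.152 in HD, 3.11-fold lower (-1.64 ± 0.11 SE, limma adjusted p = 1.1e-07). Oasl2 was 2.89-fold and Ifit1 2.38-fold lower. The HD signal of Ifit1 (5.60) lay near the HD median of the negative control rows (5.42), which limits its fold. Adjusted over the list alone, 19 fell. The camera adjusted p was 5.4e-12, and adjusted p = 0.25 with an estimated correlation. The spread of the list's mean signal was wider among LD arrays (SD 0.15) than among HD arrays (SD 0.049), and the groups did not overlap. In the list of NF-kB targets and chemokines, 7 of 20 members rose and 10 fell (8 and 11 adjusted over the list alone). The chemokine Ccl5 was 2.36-fold and the cytokine Csf2 1.53-fold lower, while the neutrophil chemokine Cxcl1 was 1.49-fold higher. The list as a whole did not pass camera (adjusted p = 0.19), except after the control-row scaling (lower, adjusted p = 0.034).

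Genes of DNA replication and ribosome production were higher in HD. Of 29 replication genes, 28 rose and none fell, with a median log2 change of 0.34. Ccne2 rose 1.98-fold (0.99 ± 0.0851 SE, limma adjusted p = 8.0e-07), Rrm2, a subunit of ribonucleotide reductase, 1.65-fold, and Rfc4 of the clamp loader 1.49-fold. Of 22 genes of ribosome biogenesis and MYC targets, 19 rose and none fell (median 0.40). The largest were Srm (spermidine synthase) and Bop1 (a ribosome assembly factor), each 1.64-fold, and Rrp12 at 1.61-fold. All 6 tested histone genes rose (median 0.35), H1f5 most at 1.44-fold; histone copies are near-identical, so single genes are uncertain. Adjusted over the list alone, 28, 20 and 6 members of these 3 lists rose. By camera, adjusted p were 1.9e-09, 3.0e-08 and 0.010, and adjusted p = 0.32, adjusted p = 0.25 and adjusted p = 0.40 with an estimated correlation. Of 28 cell cycle and mitosis genes, 21 rose and none fell (22 adjusted over the list alone), with a median of 0.17, led by Nuf2 of the kinetochore at 1.44-fold, cyclin A2 (Ccna2) at 1.22-fold and Cdk1 at 1.21-fold. Ribosomal protein genes rose by a median of 0.11, with 14 of 22 higher (15 adjusted over the list alone), led by Rpl27 at 1.20-fold. A further 22 of the 44 listed had no single-gene row. The dimmer row of Rpl27, by its identifier on another chromosome, rose by 0.24 on the log2 scale. Camera adjusted p for these 2 lists were 0.0028 and 0.030, and adjusted p = 0.55 for both with an estimated correlation. Both calls ended after quantile normalization (medians 0.13 and 0.105, adjusted p = 0.084 and 0.13), and after the control-row scaling camera placed both below other genes without a call (medians 0.03 and -0.03, adjusted p = 0.48 and 0.10), with Ccna2 at 0.08 (adjusted p = 0.19) and Rpl27 at 0.03 (adjusted p = 0.58). The ribosomal protein call was also lost with the stricter filter (adjusted p = 0.056), with array weights (0.058) and without LD replicate 4, HD replicate 1 or HD replicate 2 (adjusted p = 0.067, 0.056 and 0.053), while its median stayed at 0.09 to 0.11.

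**Figure D3:**
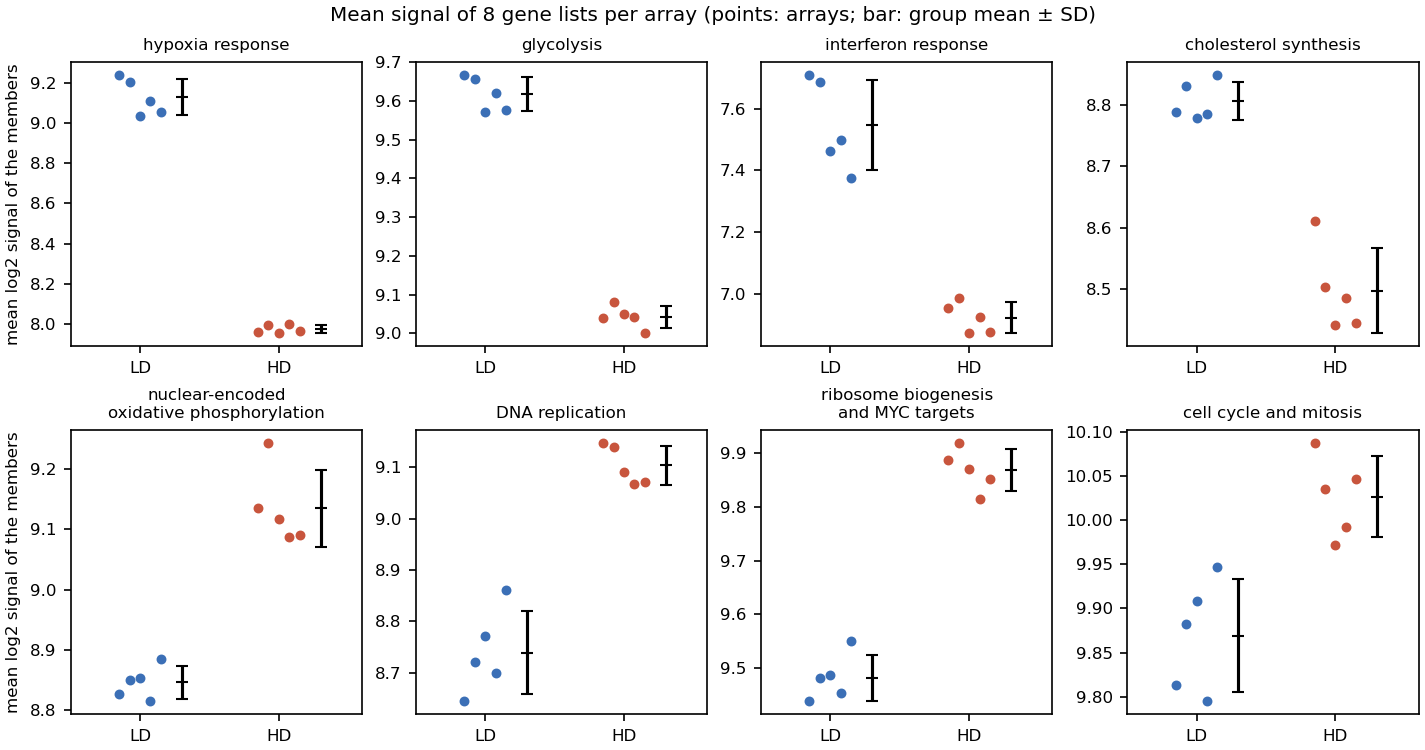
Mean log2 signal over the tested members of 8 gene lists (y axis; ranges differ and do not start at 0) on each LD (blue) and HD (red) array, with the group mean ± SD. In all 8 lists the 5 HD arrays lie on one side of the 5 LD arrays; the hypoxia list differs by -1.15 and the cell cycle list by 0.16.

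Genes of matrix remodelling went both ways. More were lower than higher in HD in each of the lists of collagen processing, proteases, matrix proteins, and integrins and collagen receptors. Of 15 collagen processing genes, 9 fell and 4 rose (median -0.20). P4ha1, a collagen prolyl 4-hydroxylase, was 2.25-fold lower (-1.17 ± 0.0536 SE, limma adjusted p = 4.1e-09) and Plod2, a lysyl hydroxylase, 1.97-fold lower, while P3h2 was 1.98-fold higher. P4ha1 and P4ha2 are also in the hypoxia list. Of 23 proteases and inhibitors, 12 fell and 5 rose (median -0.16), with Mmp9 2.15-fold, Mmp13 1.93-fold and Mmp11 1.48-fold lower. Of 23 collagens and matrix proteins, 11 fell and 3 rose (median -0.08); the largest falls were in tenascin C (Tnc, 1.55-fold), Lama5 (1.36-fold) and Lamb2 (1.29-fold). Counts were the same when adjusted over the list alone. Camera adjusted p were 0.0034, 0.0039 and 0.023, and adjusted p = 0.32, adjusted p = 0.099 and adjusted p = 0.55 with an estimated correlation. The matrix protein call was lost without HD replicate 1 (median -0.07, adjusted p = 0.067) and with array weights (median -0.09, adjusted p = 0.058). Without the filter on dim rows, the medians were -0.05 for proteases and -0.04 for matrix proteins; with the stricter filter they were -0.20 for matrix proteins and -0.32 for collagen processing. The list of integrins and collagen receptors, not all of which bind collagen, went both ways, with 5 of 17 higher and 7 lower. Itgb5 and the collagen-binding integrin subunit Itga2 were 1.40-fold and 1.38-fold lower and Sdc4 1.20-fold lower. The receptor counts did not change when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.11). It passed as lower after the control-row scaling (adjusted p = 0.0067), after quantile normalization (0.03) and without the filter on dim rows (0.048). Of 19 YAP and TAZ targets, 11 rose and 3 fell (12 and 4 adjusted over the list alone), with Ccn1 1.58-fold, Ddah1 1.49-fold and F3 1.27-fold higher. Of 19 serum response factor targets, 8 rose and 2 fell, also adjusted over the list alone, with Fosl1, Srf and Egr1 1.42-fold, 1.36-fold and 1.31-fold higher. Camera did not place these 2 lists apart (adjusted p = 0.19 and 0.16); without the filter on dim rows, the serum response factor list passed as higher (0.047).

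Some epithelial markers were lower in HD. Of 23 members, 11 fell and 2 rose (median -0.08), with Cldn4 2.13-fold, Krt19 1.69-fold and Epcam 1.52-fold lower. Of 7 luminal and milk protein genes, 4 fell and 1 rose (median -0.30); Lcn2 and Esr1 were 1.78-fold and 1.26-fold lower, and Csn3 fell from 5.77 to 4.88, below the signal floor. Both passed camera (adjusted p = 0.0031 and 0.0082), with adjusted p = 0.23 and adjusted p = 0.13 with an estimated correlation. Without the filter on dim rows, the luminal median was 0.03, with camera still lower (adjusted p = 0.013), and with the stricter filter it was -0.18. Mesenchymal markers did not pass camera as a list (adjusted p = 0.94). Of 11, S100a4 rose 1.70-fold, Twist1 1.28-fold and 1 other rose, and Fn1 fell by 0.34. Among markers of other cell types, Postn and Cd68 fell and most others did not pass the test. Of 14 listed macrophage and monocyte genes, 9 lay below the signal floor, and of the 5 tested Cd14 rose by 0.26 and Cd68, a lysosomal protein, fell by 0.74. Fibroblast genes included the matrix protein periostin (Postn, 2.48-fold lower), while Col3a1 and Thy1 differed by 0.15 and 0.12. Of the 7 tested fibroblast genes, 3 are also in other lists. Endothelial genes differed by -0.02 to 0.17, with Tie1 and Cldn5 at 0.17 and 0.16. Lymphocyte genes differed by 0.076 to 0.16, Cd3e most. Over all genes, 2 fibroblast, 1 macrophage, 2 endothelial and 1 lymphocyte gene passed as higher, and 1 fibroblast and 1 macrophage gene as lower. Adjusted over the list alone, the counts for these 7 lists were the same except that 2 macrophage genes rose. The Col3a1 call was lost without LD replicate 1, 2 or 3 or HD replicate 3, 4 or 5 (adjusted p = 0.052 to 0.087). That of Cldn5 was lost without LD replicate 1, 2 or 5 or HD replicate 1 (0.063 to 0.078), and that of Cd3e without LD replicate 2 or HD replicate 3 (0.059 and 0.055). The fibroblast, macrophage and endothelial lists did not pass camera (adjusted p = 0.86, 0.95 and 0.51), and the lymphocyte list had only 4 tested genes and was not tested.

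Stress pathways divided. Of 12 heat shock genes, 10 rose and none fell (median 0.27), led by Hsph1 at 1.83-fold, Hspe1 at 1.40-fold and Hspd1 at 1.31-fold. Of 17 NRF2 targets, 12 rose and 4 fell (median 0.21), with Nqo1 1.74-fold, Gclc 1.43-fold and Slc7a11 1.40-fold higher. Of 19 autophagy and lysosome genes, 12 fell and 2 rose (13 and 3 adjusted over the list alone; median -0.13), with Sqstm1 and Gabarapl1 1.36-fold and 1.24-fold lower and Atp6v1h 1.26-fold higher. Camera adjusted p were 0.0015, 0.023 and 0.0014, and adjusted p = 0.099, adjusted p = 0.40 and adjusted p = 0.32 with an estimated correlation. The heat shock and NRF2 calls ended under the control-row scaling (medians 0.20 and 0.06, adjusted p = 0.18 and 0.98). The NRF2 call also ended after quantile normalization (median 0.26, adjusted p = 0.11), with the stricter filter (0.21, 0.074) and without HD replicate 2 (0.205, 0.058). Of 20 ATF4 targets, 9 rose and 6 fell; Asns rose by 0.58 on the log2 scale while Ddit4 and Vldlr were 3.22-fold and 1.49-fold lower. Of 18 unfolded protein response genes, 9 rose and 3 fell, with Dnajb11 and Creld2 1.47-fold and 1.32-fold higher and Xbp1 1.33-fold lower. Of 15 p53 targets, 7 rose and 3 fell (7 and 4 adjusted over the list alone); Gadd45a was 2.01-fold lower and Plk2 1.65-fold higher, and Trp53inp1 fell from 6.58 to 5.29, close to the signal floor. Counts not given otherwise were the same when adjusted over the list alone. These 3 lists did not pass camera (adjusted p = 0.86, 0.36 and 0.86).

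Signalling lists without a common direction held genes called either way, as did the genes tested as a whole, of which 50.9% were called. Of 15 TGF-beta targets, 4 rose and 6 fell; Id1 and Id3 rose 2.22-fold and 1.54-fold and Pmepa1 was 1.65-fold lower. Of 13 WNT and Notch targets, 4 rose and 3 fell, with Lef1 and Hes1 1.40-fold and 1.22-fold lower and Nrarp 1.27-fold higher. Of 15 ERK outputs, 6 rose and 4 fell (6 and 5 adjusted over the list alone), with Fosl1 and Spry4 1.42-fold and 1.33-fold higher and Ier3 1.37-fold lower. The TGF-beta, WNT and Notch counts were the same when adjusted over the list alone. None of the 3 lists passed camera (adjusted p = 0.27, 0.96 and 0.95). The median, mean and camera direction differed in sign for the fatty acid oxidation, p53, mesenchymal, fibroblast, TGF-beta and WNT and Notch lists. In all, 23 of the 40 lists tested passed camera with the preset correlation, 12 higher and 11 lower. None passed with estimated correlations, where the smallest adjusted p was 0.099 and 7 lists had an unadjusted p under 0.05; fry, which tests a list's own genes without comparing them with others, called 30. The mean signal of a list was also compared between the 5 HD and 5 LD arrays by a two-sided exact permutation test. For 26 of 40 lists this test gave its smallest possible p of 0.0079 (adjusted p = 0.012). It does not compare a list with other genes, of which 36.7% had groups that did not overlap. Lists that did not pass camera, such as the unfolded protein response and YAP and TAZ targets, reached this p too.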

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

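The tests of the background rows and of the unannotated rows below were chosen after their values were seen. Among values outside the gene comparison, the rows named as negative controls were lower in HD (array medians differed by -0.25, 95% interval -0.39 to -0.11) while the 23 background rows were higher (0.16). Of 14039 transcript clusters above the floor without a single gene symbol, 1337 were higher and 4728 lower in HD (limma, adjusted p under 0.05), a split opposite to that of the named genes; 4 rose and 53 fell by at least 1 on the log2 scale.

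The fall of the negative control rows was weighed against technical sources. A lower background signal might lower the background rows too, but these rose by 0.16 (95% interval 0.081 to 0.25). RMA had already subtracted a modelled background and equalised the intensities between arrays. The background rows therefore cannot decide whether the background signal was lower in HD. An effect of the normalization on all rows of that signal level would lower the transcript clusters in the same 20 signal bins, but their median difference was 0.026 against -0.21 for the negative control rows. Rows without a gene symbol fell relative to single-gene rows, by -0.14 (95% interval -0.21 to -0.069, two-sided exact permutation p = 0.0079). That is consistent with less signal from unannotated or unspliced RNA in HD, a hypothesis, and whether this reflects the cells, genomic DNA or RNA quality stays open.

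A single array stood apart from the other 4 of its group by Dixon's ratio in 16 of 352 group checks, where chance gives about 1 in 20, or 17.6. Among genes, the ratios were 0.759 for Adm (HD replicate 4), 0.725 for Atp5l, 0.772 for Acadvl and 0.721 for S100a4 (all HD replicate 2), 0.851 for Cldn5 (HD replicate 1) and 0.749 for Cd3e (HD replicate 3). In LD they were 0.811 for Taldo1 and 0.831 for Hspd1 (replicate 1), 0.803 for Insig1 and 0.824 for Twist1 (replicate 2), 0.833 for Hes1 (replicate 4) and 0.800 for Bop1 (replicate 5). Among list means, they were 0.872 for NRF2 targets and 0.719 for autophagy and lysosome (HD replicate 2) and 0.884 for fibroblast markers (LD replicate 4). The median over all rows was low in HD replicate 2 (5.19 against 5.24 for the others, ratio 0.716). The design has 1 contrast, so no subgroups were compared.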

How the results depend on the processing

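The control-row scaling and the fits without both LD replicate 1 and HD replicate 3 were chosen after seeing the data. Leaving out 1 array gave 4704 to 5603 genes higher and 3063 to 3506 lower in HD, and 21 to 23 lists. Adjusted p over these fits ran from 1.0e-23 to 1.0e-20 for hypoxia, 2.0e-14 to 9.2e-13 for glycolysis, 1.8e-12 to 1.0e-10 for oxidative phosphorylation, 0.0022 to 0.0083 for the TCA cycle, 0.30 to 0.82 for mitochondrially encoded transcripts, 0.0011 to 0.0060 for serine and one-carbon, 2.1e-04 to 7.0e-04 for glutamine, 0.017 to 0.034 for pentose phosphate, 2.9e-09 to 3.3e-07 for cholesterol, 0.0084 to 0.020 for fatty acid synthesis and 0.24 to 0.42 for fatty acid oxidation. Requiring 1.5-fold left 138 higher and 278 lower genes, by construction. All rows, named or not, gave 8329 lower against 6730 higher rows, so that 44.7% of calls were higher. Quantile normalization gave 7637 higher and 2955 lower genes and median centring 6601 and 2914 (72.1% and 69.4% higher), and 8125 of 9055 and 8503 of 9056 original calls kept their direction and stayed past the threshold. Control-row scaling gave 8778 higher and 3396 lower; 7038 of 9052 original calls were kept and 141 were called the opposite way. With an estimated correlation 0 lists passed, with adjusted p of 0.099 for hypoxia and glycolysis, 0.25 for cholesterol and glutamine, 0.32 for oxidative phosphorylation, pentose phosphate and fatty acid synthesis, and 0.40 for the TCA and serine lists. Pentose phosphate was lost after quantile normalization (0.065) and fatty acid synthesis with the stricter filter (0.095). Control-row scaling ended the calls of the TCA (0.62), glutamine (0.088) and pentose phosphate (0.22) lists, whose medians were 0.15, 0.28 and 0.17 against 0.17, 0.31 and 0.20, while the median of all genes rose from 0.055 to 0.13, and called the mitochondrially encoded list lower (0.0024). It placed cell cycle (0.48) and ribosomal proteins (0.10) below other genes, without a call, with medians of 0.03 and -0.03, and turned ND3 to -0.15. Where no cause is given, the cause was not tested. Without both extreme arrays, 4444 genes were higher and 2848 lower. The replicate block gave 5654 higher and 3404 lower genes; 1 of 10 arrays correlated best with its own number in the other group, so the block carries no pairing. Under the alternatives fixed in advance, other than leaving out an array, 1012 values of named genes kept their direction and side of the threshold, 6 lost their call (ND6 3 times, Col3a1, Cldn5 and Cd3e) and 0 reversed. The negative and positive control rows, on which the control-row scaling rests, differ between the groups, so its values are uncertain. Signals near the negative control rows limit what can be said of dim genes. Besides the 23 list calls lost with an estimated correlation, 9 calls of lists were lost over the other alternatives fixed in advance, leave-outs aside.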

Other observations

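The gene families below, the control-row scaling and the test of mitochondrially encoded transcripts were chosen after the values were seen. Of 193 families of 8 or more tested genes that share the letters of their symbols, with members of the fixed lists left out, 14 were higher and 6 lower in HD by camera with the preset correlation, and 0 with estimated correlations. Transcripts of mitochondrial ribosomal proteins rose (Mrpl, 41 of 47 higher and 1 lower, median log2 change 0.25, adjusted p = 1.6e-07; Mrps, 25 of 28 higher, median 0.24, adjusted p = 1.0e-05), each with adjusted p = 0.80 with an estimated correlation. Transcripts for mitochondrial import rose as well (Timm, 10 of 14, median 0.35; Tomm, 7 of 8, median 0.30), as did those for proteasome regulatory subunits (Psmd, 13 of 14, median 0.27), RNA exosome subunits (Exosc, 9 of 9, median 0.26) and nucleoporins (Nup, 15 of 17, median 0.24). Their adjusted p were 0.0040, 0.016, 8.6e-04, 0.0043 and 4.0e-04, and 0.80 with an estimated correlation.

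Among families that were lower, 7 of 8 protocadherin beta genes fell (Pcdhb, median -0.69, adjusted p = 3.6e-06, and adjusted p = 0.54 with an estimated correlation), with Pcdhb20 1.97-fold, Pcdhb19 1.91-fold and Pcdhb17 1.69-fold lower; these clustered genes are similar in sequence, so single members are uncertain. Of 11 Parp genes, 10 fell (median -0.27), with Parp14 2.07-fold and Parp9 1.92-fold lower (adjusted p = 7.5e-06, and adjusted p = 0.80 with an estimated correlation). Zinc finger genes named Zfp were more often lower (108) than higher (33) of 310, with a median of -0.064 (adjusted p = 1.5e-05, and adjusted p = 0.80 with an estimated correlation). This median became -0.0044 after quantile normalization and 0.042 after control-row scaling. The other families named here kept their direction under quantile normalization, median centring and control-row scaling. The median of all genes tested rose to 0.09, 0.077 and 0.13 in these settings, so direction alone does not set a higher family apart. After control-row scaling the medians of Psmd, Nup and Tomm fell to 0.18, 0.21 and 0.23. Those of Mrpl, Mrps, Timm and Exosc were 0.29, 0.30, 0.39 and 0.38.

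The number of calls was set against 100 splits of the 10 arrays into 5 and 5, the real one included. Only 1 of the 100, the real split, gave 5589 genes in one direction, and only 1 gave 3467. The highest other split gave 0 genes. In the other splits the difference between HD and LD adds to the spread within groups, which lowers their counts. Low counts there were thus likely in advance, so these splits cannot decide whether chance gave the real counts. For lists, 4 of 100 splits gave 23 or more, and the highest other split also gave 23. The splits that kept 4 LD arrays together gave a median of 19 lists and those that kept 3 together a median of 7 and up to 16, with no gene called in any. The share lies under 0.05, but mixed groups reached the real count, so the number of lists does not set the real split apart. These groups still hold part of the difference between HD and LD, and no test separated that from another structure of the samples.

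The fall of hypoxia and glycolysis genes (39 members, median log2 change -0.68) was weighed against 2 technical sources. After each array was scaled on its control rows the median was -0.77 (95% bootstrap interval over members -1.1 to -0.61). That interval treats the members as independent, while their estimated correlations were 0.46 (hypoxia) and 0.3 (glycolysis). It does not measure the spread between arrays. That the median did not rise argues against a difference in signal contrast as the source of the fall. This holds only as far as the control rows, which differ between the groups, measure that contrast. After quantile normalization the medians of the hypoxia and glycolysis lists were -1.07 and -0.41. Without any 1 array the median was at most -0.65, so no single array carries it. Oxygen and the number of cells after culture are not given in these data, and no biological explanation was tested.

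The rise of nuclear oxidative phosphorylation genes (median 0.26) was weighed in the same way. It lay at percentile 100 of 10000 random lists matched on mean expression and gene span, which argues against these as its whole source. Genes of the random lists were drawn independently, while those of this list had an estimated correlation of 0.39. The percentile is thus no measure of chance. After control-row scaling the list median was 0.27 (95% bootstrap interval over members 0.21 to 0.34), with the same limits on the interval and the control rows. The median of all genes tested rose from 0.055 to 0.13 under that scaling, so the list stood less far above other genes. The scaling thus argues against signal contrast as the whole source, but not as a part of it. After quantile normalization the list median was 0.29. Transcripts of mitochondrial DNA below log2 13, where saturation is less of a concern, did not rise with it: 5 rows differed by -0.0080 (95% interval -0.11 to 0.090). This argues against a rise of mitochondrial transcripts from both genomes. No biological explanation was tested.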
